A study of Homo sapiens with 8 samples.

How the data were processed

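Total RNA of MCF7 cells was reverse transcribed from an oligo(dT)-T7 primer, labelled with biotin and hybridized to 8 single-channel oligonucleotide arrays, per the labels. The deposited values are linear signal intensity per probe set, and each array had been scaled to a mean of 500 over all probe sets with the lowest and highest 2% left out (500.067 to 500.083 on the 8 arrays). They had not been log-transformed or quantile-normalized. The software that made them is not given in the sources used here, and no detection calls came with them. All 8 arrays were used, in 4 groups of 2: control, ARC, sangivamycin and doxorubicin. The groups were taken from the titles and the treatment protocol, and the description of every sample, treated ones included, calls it a control dataset. The number of arrays limits the precision.

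The table holds 54675 probe sets. The annotation given with it pairs 41097 of them with 1 gene, 1801 with several and leaves 11777 unlisted, and 62 control probe sets were left out of the gene tests. Of the probe sets with 1 gene, 41043 matched a gene identifier of the reference. Genes were named from probe sets with 1 gene only, and fold changes of families of near-identical genes may mix their members. A probe set was kept if its highest group mean lay above the 40th percentile of all values (a signal of 53.66), which left 39818, and each of 16018 genes was represented by its probe set with the highest mean.

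Signals were transformed to log2(value + 16), on which fold changes of dim genes are understated, and fitted in limma 3.58.1 under R 4.3.3 with all 4 groups in 1 linear model and an intensity trend in the prior variance. The fit had 4 residual and 7.19 prior degrees of freedom, and the median residual SD was 0.26 log2. Each drug was compared with control and with each other drug, 6 comparisons in all. Genes were called changed at a Benjamini-Hochberg adjusted p below 0.05. On simulated data with 200 genes changed among 16018, the ARC comparison recovered 11.9% of 1.5-fold, 29.9% of 2-fold and 57.6% of 4-fold changes, and called 4 of 15818 unchanged genes. The simulation changed far fewer genes than the 5988 called in ARC against control. Its adjusted threshold was therefore stricter, and these rates may understate recovery in the data. Even so, genes not called are not shown to be unchanged.

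Sets of genes, 31 lists written from general knowledge, were tested with camera at an assumed correlation between genes of 0.01 and adjusted over 186 tests. Camera asks whether a list moves relative to all other genes, so a shift of the whole scale does not by itself move it. Counts of list members past the threshold are adjusted over all genes and, beside that, over the list alone. Correlations of fold changes are Pearson correlations over the genes tested, without p-values, since genes are not independent.

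The tests, the lists, the filter, the alternatives and the rule for naming genes were chosen before the data were examined. The rule names, in each comparison, the 10 largest rises and 10 largest falls among genes past the threshold with both arrays of 1 group beyond both of the other, up to 4 members of a list with the smallest p-values, and a fixed set of targets and markers. The latter are MYC, MCL1, HEXIM1, CDK9, CCNT1, POLR2A, CDKN1A, MDM2, TP53, ESR1, PRKCA, PRKCD, PRKCE, TOP2A, TOP2B, ADK, SLC29A1, CCND1, BCL2 and BIRC5. Where the text gives fewer members of a list, they are examples from those 4. Alternatives were 2 other added constants, 2 other filters, quantile normalization, scaling to the hybridization spike-ins, all probe sets, no trend in the prior variance, only the 2 groups compared, the array number as a replicate block, each array left out in turn, and for lists the correlation estimated from the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.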

Results

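MCF7 cells, an established estrogen receptor-positive breast cancer line, were grown in RPMI medium with serum and profiled on 8 single-channel oligonucleotide arrays. Control cells received no treatment. The other cells were exposed for 24 h to 2 µM ARC, 2 µM sangivamycin or 2 µM doxorubicin, with 2 arrays in each of the 4 groups. The groups were read from the sample titles and the treatment protocol, since every sample's description calls it a control dataset. ARC and sangivamycin are nucleoside analogs, and ARC carries a hydrazino group that sangivamycin lacks. Both have been studied as inhibitors of P-TEFb, the kinase complex that releases paused RNA polymerase II, and of protein kinase C. Doxorubicin is an anthracycline that traps topoisomerase II on DNA. Setting ARC beside the other drugs asks how alike the 3 profiles are. The sources used here do not say whether the 2 arrays of a group are separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Signals are given as mean ± SD of 2 arrays, and changes as log2 fold change ± SE with limma adjusted p-values.

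Each drug left its own mark on the MCF7 transcriptome. Over the 16018 genes tested, the 2 arrays of a group correlated at 0.978 in controls, 0.965 in ARC, 0.953 in sangivamycin and 0.973 in doxorubicin. Between groups the correlations were lower. They were 0.92 to 0.937 for ARC with sangivamycin, 0.901 to 0.912 for ARC with control, 0.861 to 0.874 for ARC with doxorubicin and 0.845 to 0.846 for sangivamycin with doxorubicin. Sangivamycin array 2 stood apart in a measure of RNA quality, the 3'/5' signal ratio, which was 5.34 for ACTB and 2.3 for GAPDH, against 1.15 to 1.51 and 0.99 to 1.17 on the other 7 arrays. It also held the highest signals of 10 of 13 fibroblast and stromal genes, of 6 of 13 leukocyte genes and of the blood gene HBB. No other array held the highest signal of more than 2 of the stromal or 4 of the leukocyte genes. In controls the mean signal lay above the filter value of 53.66 for 6 of the stromal and 4 of the leukocyte genes. HBB read 5454 on sangivamycin array 2 and 173 on sangivamycin array 1, and COL3A1 read 681.7 and 39.4. For this reason the total numbers of genes changed by sangivamycin are also given without that array, while the other counts include it.

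**Figure D1:**
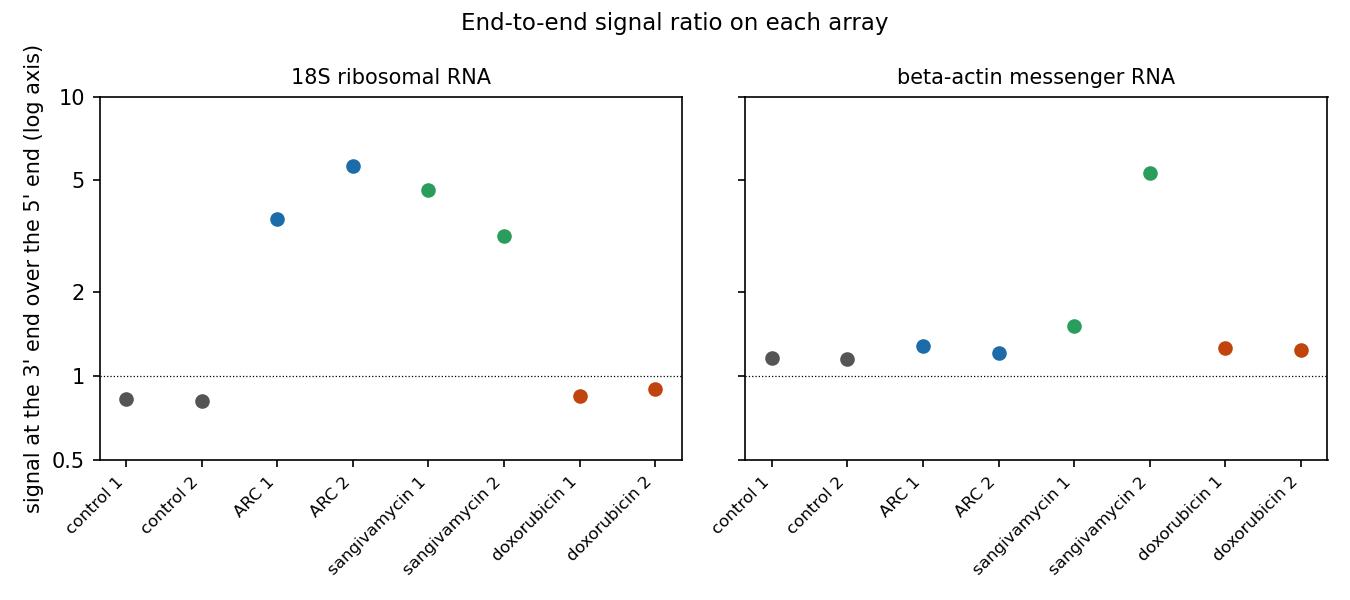
Ratio of the 3' to the 5' signal (log axis) of actin and of 18S rRNA on each of the 8 arrays, one point per array. Actin stands out only on sangivamycin array 2 (5.34), and 18S lies between 3.15 and 5.65 on the 4 nucleoside arrays and between 0.811 and 0.898 on the other 4.

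ARC changed 5988 genes against control, sangivamycin 5985 and doxorubicin 5578. Of these, 2529 rose and 3459 fell in ARC, 2525 rose and 3460 fell in sangivamycin, and 2654 rose and 2924 fell in doxorubicin. At least 2-fold, 1406 genes rose and 1853 fell in ARC, 1476 rose and 1867 fell in sangivamycin, and 1567 rose and 1523 fell in doxorubicin. The split into rises and falls depends on the scaling. Each array had been brought to the same trimmed mean, and scaling to the hybridization spike-ins instead shifted the median gene by -0.174 log2 in ARC, -0.642 in sangivamycin and 0.426 in doxorubicin. The share of changed genes that rose was then 28.2% in ARC (966 of 3426), 9.1% in sangivamycin (524 of 5758) and 77.1% in doxorubicin (2787 of 3614), against 42.2%, 42.2% and 47.6%. Gene lists moved with the scaling too, and the counts and median with spike-in scaling follow where any of them shifted by over 1.5 times or turned. The spike-in signals themselves differed between the arrays of a group, most in ARC (0.456 and -0.282 log2 from the mean of all arrays). Counts and calls with spike-in scaling carry that added spread. Whether total RNA per cell changed cannot be read from these arrays.

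**Figure D2:**
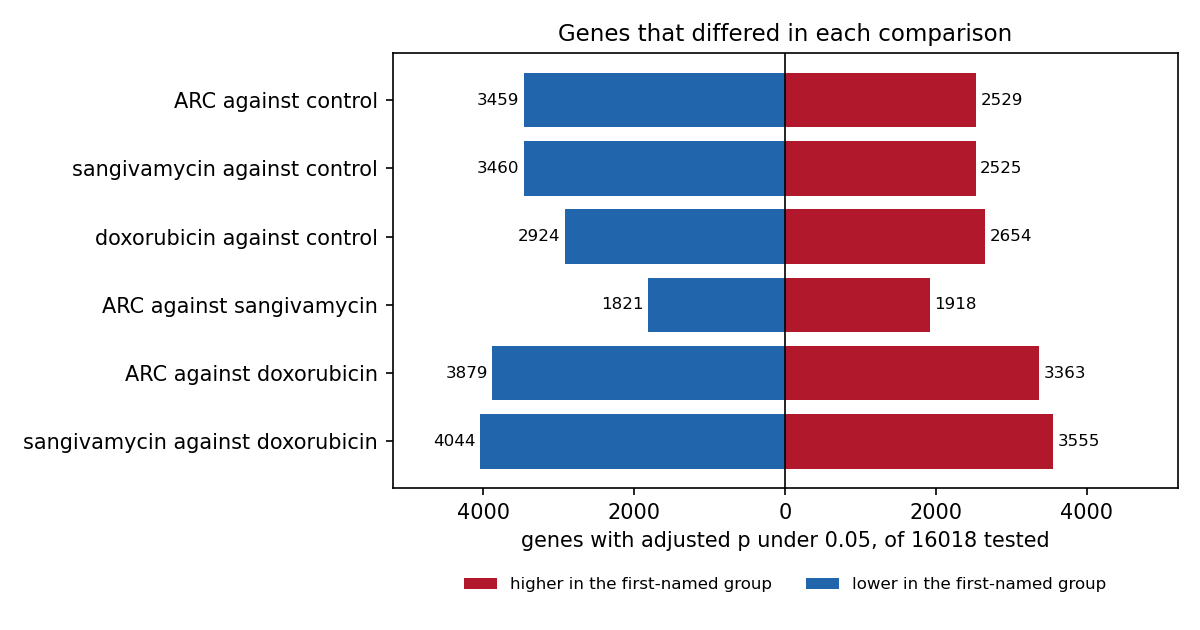
Number of genes past the threshold in each of the 6 comparisons. Genes higher in the first group are drawn to the right of 0 and genes lower in it to the left. The 2 nucleosides changed nearly the same number of genes against control (5988 and 5985), and the fewest genes separated ARC from sangivamycin (3739).

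ARC raised p53 targets in MCF7 cells. The stress cytokine GDF15 went from a signal of 217.5 ± 21.1 in controls to 21600 ± 836 in ARC, a rise of 6.53 ± 0.11 log2 (adjusted p = 4.9e-11). The cyclin-dependent kinase inhibitor CDKN1A rose from 849.3 ± 12.8 to 29840 ± 3570 (5.1 ± 0.13, adjusted p = 1e-09), GADD45A by 6.3 ± 0.12 (adjusted p = 9e-11) and the stress transcription factor ATF3 by 5.63 ± 0.12 (adjusted p = 2.2e-10). In the opposite direction the proto-oncogene MYC fell from 10030 ± 362 to 1365 ± 122, by 2.87 ± 0.12 log2 (adjusted p = 5.9e-08), and the estrogen receptor gene ESR1 fell from 6538 ± 154 to 1172 ± 21.9, by 2.46 ± 0.12 (adjusted p = 2e-07). The 10 largest rises, from 4.88 to 6.53 log2, were those of GDF15, GADD45A, ATF3, LIF, ND6, CDKN1A, C1orf162, FOSL1, PRICKLE2 and RASD1. The 10 largest falls, from -3.43 to -5.15, were those of MNX1-AS1, ZBTB42, SLC2A10, COX3, AQP11, CRISPLD1, IGSF9, MILIP, LPCAT4 and PRIMA1. In 4 of the rises and 9 of the falls the lower signal lay under the filter value of 53.66, so their size and order are uncertain.

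The p53 target list moved almost as a whole in ARC. There 27 of 28 measured members rose (27 adjusted over the list alone). The median change was 2.27 log2 (camera adjusted p = 1.1e-22, adjusted p = 0.017 with an estimated correlation). MDM2, the p53 antagonist that p53 itself induces, rose by 2.38 ± 0.15 (adjusted p = 1.1e-06). The death receptor FAS and the BH3-only gene PMAIP1 rose by 4.03 ± 0.13 (adjusted p = 7.3e-09) and 3.62 ± 0.16 (adjusted p = 5.9e-08). Genes of the integrated stress response moved the same way. Here 13 of 20 measured members rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 1.7e-08, adjusted p = 0.051 with an estimated correlation), led by ATF3, SESN2, DDIT4 and DDIT3. Spike-in scaling put 11 up among the stress response genes, at a median of 1.03 log2. ATF3 is also in the list of short-lived transcripts, and SESN2 in that of p53 targets. Short-lived transcripts split from MYC, since 25 of 43 measured members rose and 3 fell (26 and 5 adjusted over the list alone; camera adjusted p = 1.7e-08, adjusted p = 0.11 with an estimated correlation). IER5 was up 3.1 ± 0.13 (adjusted p = 5.2e-08) and KLF10 up 2.81 ± 0.12 (adjusted p = 6.6e-08). KRAB zinc finger genes, a large family of transcriptional repressors, rose in part. There 25 of 43 measured members rose and 5 fell (26 and 5 adjusted over the list alone; camera adjusted p = 7.8e-07, adjusted p = 0.065 with an estimated correlation). Among the KRAB genes spike-in scaling put 14 up and 3 down, at a median of 0.71 log2. Among them ZNF140 was up 2.96 ± 0.14 (adjusted p = 1.3e-07) and ZNF268 up 2.52 ± 0.18 (adjusted p = 2e-06). Of the replication-dependent histones, 10 of 24 measured members rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.0012, adjusted p = 0.22 with an estimated correlation). Spike-in scaling put 4 up among the histones, at a median of 0.47 log2. Of the splicing factors, 19 of 34 measured members rose and 1 fell (22 and 1 adjusted over the list alone; camera adjusted p = 5.2e-06, adjusted p = 0.26 with an estimated correlation). Among the splicing factors spike-in scaling put 6 up, at a median of 0.24 log2.

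Of the DNA replication genes in ARC, 1 of 31 measured members rose and 21 fell (1 and 24 adjusted over the list alone; camera adjusted p = 1e-08, adjusted p = 0.066 with an estimated correlation). Spike-in scaling put 18 down among the replication genes, at a median of -1.14 log2. The helicase subunit MCM3 fell from 8291 ± 50.4 to 2480 ± 267 (-1.74 ± 0.11, adjusted p = 1.2e-06). Of the cyclins and E2F targets of G1/S, 2 of 24 measured members rose and 17 fell (2 and 18 adjusted over the list alone; camera adjusted p = 2.7e-05, adjusted p = 0.13 with an estimated correlation), led by RRM2, CCNE2, UHRF1 and CCNE1. Among the G1/S genes spike-in scaling put 1 up and 12 down, at a median of -1.14 log2. Of the DNA repair genes, 1 of 31 measured members rose and 16 fell (1 and 16 adjusted over the list alone; camera adjusted p = 2.7e-05, adjusted p = 0.11 with an estimated correlation). Spike-in scaling put 15 down among the DNA repair genes, at a median of -0.93 log2. Mitotic genes did not move as a group. There 13 of 43 measured members rose and 16 fell (14 and 17 adjusted over the list alone; camera adjusted p = 0.66). Among the mitotic genes spike-in scaling put 11 down, at a median of -0.25 log2. Of the estrogen-responsive genes, 7 of 28 measured members rose and 17 fell (7 and 17 adjusted over the list alone; camera adjusted p = 0.0015, adjusted p = 0.14 with an estimated correlation). Spike-in scaling put 2 up and 14 down among the estrogen-responsive genes, at a median of -0.99 log2. Among them CA12 was down 2.69 ± 0.14 (adjusted p = 3.1e-07), GREB1 down 2.85 ± 0.2 (adjusted p = 1.6e-06) and MYB down 2.79 ± 0.17 (adjusted p = 9.2e-07). Of the luminal identity genes, 3 of 19 measured members rose and 9 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.012, adjusted p = 0.22 with an estimated correlation). Among the luminal genes spike-in scaling put 1 up and 9 down, at a median of -0.72 log2. Cholesterol synthesis and glycolysis genes leaned down, with 7 of 17 and 8 of 19 measured members falling (camera adjusted p = 0.0096, adjusted p = 0.15 with an estimated correlation; camera adjusted p = 0.006, adjusted p = 0.33 with an estimated correlation). Spike-in scaling put 6 down among the cholesterol genes, at a median of -0.86 log2. Among the glycolysis genes spike-in scaling put 7 down, at a median of -0.55 log2.

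The named targets of the nucleosides changed one by one in ARC. Of the P-TEFb subunits, CCNT1 rose by 1.83 ± 0.15 (adjusted p = 4.1e-06) and CDK9 by 0.94 ± 0.19 (adjusted p = 0.0027), and the P-TEFb inhibitor HEXIM1 by 0.46 ± 0.11 (adjusted p = 0.0063; adjusted p = 0.056 without control array 2). The list of P-TEFb and its partners did not move as a whole, although 9 of 19 measured members rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.12). Spike-in scaling put 4 up and 2 down in the P-TEFb list, at a median of -0.2 log2. POLR2A did not pass at -0.3 ± 0.19 (adjusted p = 0.26). Of the protein kinase C family, 7 of 12 measured members fell (7 adjusted over the list alone; camera adjusted p = 0.035, adjusted p = 0.28 with an estimated correlation). PRKCD fell by 1.43 ± 0.26 (adjusted p = 0.0013) and PRKCE by 1.55 ± 0.44 (adjusted p = 0.016; adjusted p = 0.1 without control array 2), while PRKCA did not pass at -0.02 ± 0.43 (adjusted p = 0.97). The short-lived survival gene MCL1 rose by 0.73 ± 0.11 (adjusted p = 0.00025) and BIRC5 by 1.23 ± 0.16 (adjusted p = 0.00012), whereas BCL2 fell by 2.72 ± 0.17 (adjusted p = 9e-07) and CCND1 by 0.97 ± 0.12 (adjusted p = 0.00011). The nucleoside transporter gene SLC29A1 fell by 2.56 ± 0.43 (adjusted p = 0.00066), TOP2A by 0.89 ± 0.14 (adjusted p = 0.00039) and TOP2B by 0.83 ± 0.11 (adjusted p = 0.00016), and adenosine kinase ADK did not pass at -0.2 ± 0.11 (adjusted p = 0.18). TP53 itself was not tested, since the annotation used here lists no probe set for it. With spike-in scaling the calls of CDK9, HEXIM1 and MCL1 ended in ARC, and without a trend in the prior variance that of HEXIM1. The call of the protein kinase C list ended with spike-in scaling (adjusted p = 0.05) and without ARC array 1 (adjusted p = 0.089). Another probe set of LPCAT4, MYB and TOP2A moved the opposite way past the threshold in ARC. No other probe set of CDK9 or PRKCE passed in ARC.

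**Figure D3:**
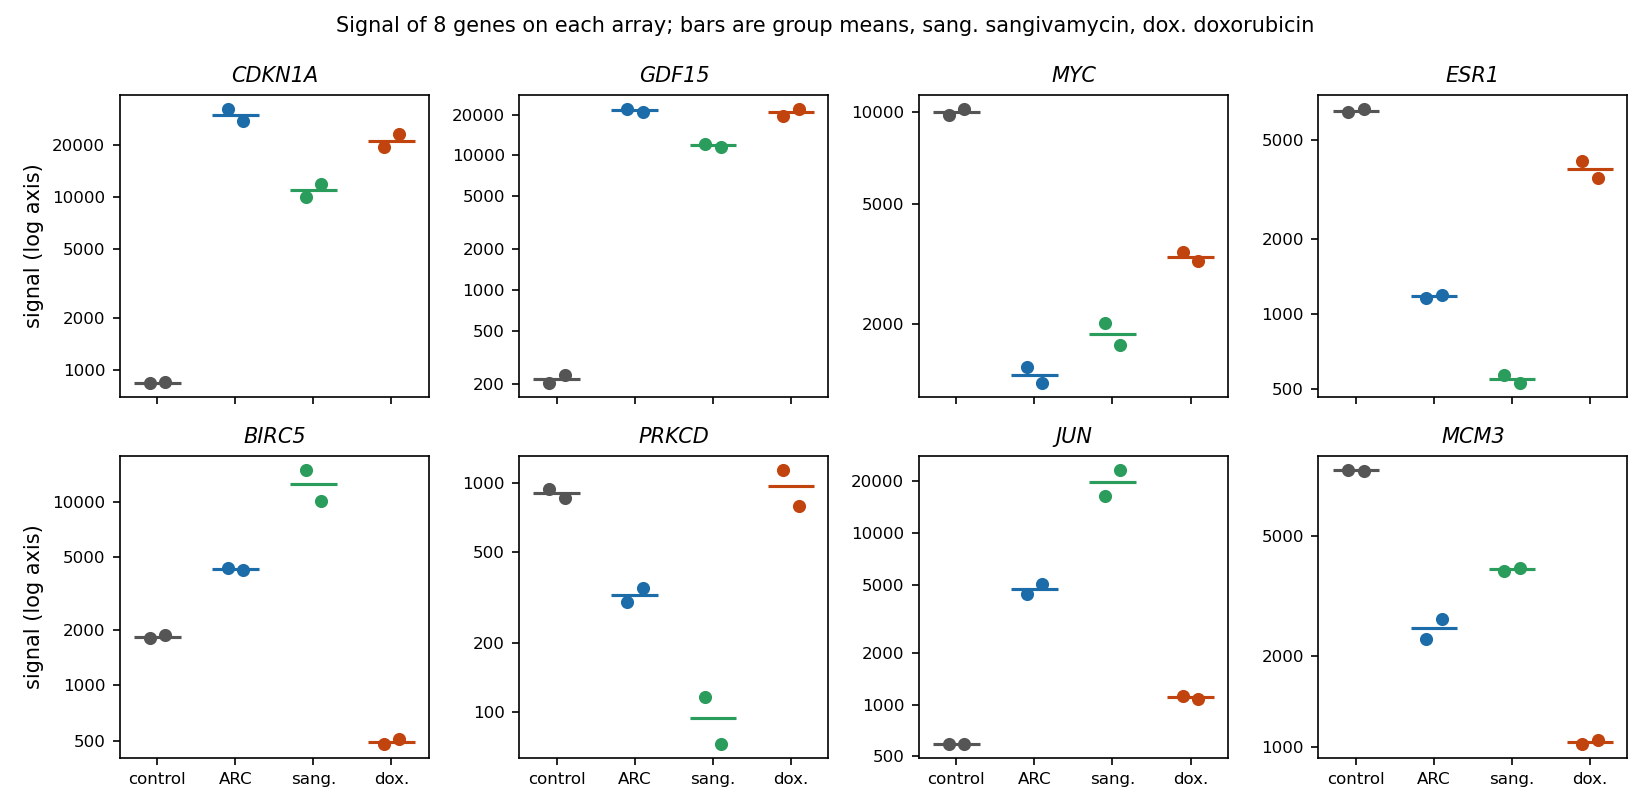
Signal (log axis) of CDKN1A, GDF15, MYC, ESR1, BIRC5, PRKCD, JUN and MCM3, one point per array and a bar at each group mean, for control, ARC, sangivamycin and doxorubicin. CDKN1A and GDF15 rose and MYC and MCM3 fell in all 3 drugs, whereas BIRC5 rose in the 2 nucleosides and fell in doxorubicin.

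Sangivamycin brought out many of the same genes as ARC. GDF15 rose from 217.5 ± 21.1 to 11860 ± 405 (5.67 ± 0.11, adjusted p = 2e-10), CDKN1A from 849.3 ± 12.8 to 10960 ± 1330 (3.66 ± 0.13, adjusted p = 1.1e-08), and the immediate early gene JUN from 588.1 ± 1.52 to 19940 ± 4960 (5.02 ± 0.16, adjusted p = 4.1e-09). ESR1 fell from 6538 ± 154 to 545.8 ± 28.7, by 3.55 ± 0.12 log2 (adjusted p = 8.6e-09), and MYC from 10030 ± 362 to 1859 ± 219, by 2.43 ± 0.12 (adjusted p = 1.7e-07). The 10 largest rises, from 5.23 to 6.61 log2, were those of FNIP1, LINC00115, CCN2, ATF3, RPPH1, GDF15, EDN1, SLC30A1, ND6 and RASD1. The 10 largest falls, from -3.58 to -5.26, were those of MYBL1, MNX1-AS1, FCHSD2, LYPD3, ZBTB42, PCYOX1L, ITGA2, SLX4, KIF13A and EMILIN3. The lower signal lay under 53.66 in 3 of the rises and 5 of the falls, whose size and order are uncertain. Without sangivamycin array 2, 5664 genes changed, 2146 up and 3518 down, and 4919 of them were shared with the 5985. Without control array 1 the count was 3852, and without control array 2 it was 3968.

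Of the p53 targets in sangivamycin, 17 of 28 measured members rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 1.03 log2 (camera adjusted p = 1.4e-10, adjusted p = 0.036 with an estimated correlation). Among the p53 targets spike-in scaling put 11 up and 3 down, at a median of 0.31 log2. Short-lived transcripts had a median of 1.61 log2. There 33 of 43 measured members rose and 3 fell (34 and 3 adjusted over the list alone; camera adjusted p = 7.6e-19, adjusted p = 0.059 with an estimated correlation). Spike-in scaling put 21 up and 3 down among the short-lived transcripts, at a median of 0.89 log2. KLF10 was up 4.26 ± 0.12 (adjusted p = 2.2e-09) and IER5 up 4.07 ± 0.13 (adjusted p = 4.6e-09). Of the NF-kappaB targets, 9 of 20 measured members rose (11 and 1 adjusted over the list alone; camera adjusted p = 9e-04, adjusted p = 0.11 with an estimated correlation). Among the NF-kappaB targets spike-in scaling put 6 up and 3 down, at a median of 0.57 log2. Among them were the inhibitor NFKBIA (2.1 ± 0.12, adjusted p = 3.4e-07) and the cytokine IL6 (3.07 ± 0.31, adjusted p = 2.1e-05), whose control signal of 45.92 ± 4.13 lay under 53.66 and leaves the size uncertain. Of the replication-dependent histones, 16 of 24 measured members rose (19 adjusted over the list alone; camera adjusted p = 1e-08, adjusted p = 0.1 with an estimated correlation). Spike-in scaling put 8 up among the histones, at a median of 0.84 log2. H2BC21 was up 2.44 ± 0.14 (adjusted p = 4.4e-07). Of the integrated stress response genes, 10 of 20 measured members rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 3.2e-05, adjusted p = 0.074 with an estimated correlation). Among the stress response genes spike-in scaling put 7 up and 1 down, at a median of -0.29 log2. Of the splicing factors, 19 of 34 measured members rose and 3 fell (19 and 4 adjusted over the list alone; camera adjusted p = 5.4e-05, adjusted p = 0.3 with an estimated correlation). Spike-in scaling put 1 up and 6 down among the splicing factors, at a median of -0.31 log2. The splicing call ended with spike-in scaling (adjusted p = 0.27). Of the DNA replication genes, 4 of 31 measured members rose and 20 fell (4 and 21 adjusted over the list alone; camera adjusted p = 3.5e-05, adjusted p = 0.11 with an estimated correlation). Among the replication genes spike-in scaling put 24 down, at a median of -1.42 log2. MCM3 was down 1.09 ± 0.11 (adjusted p = 2.5e-05). Of the G1/S cyclins and E2F targets, 12 of 24 measured members fell (1 and 15 adjusted over the list alone; camera adjusted p = 0.0025, adjusted p = 0.22 with an estimated correlation). Spike-in scaling put 18 down among the G1/S genes, at a median of -1.21 log2. Of the DNA repair genes, 18 of 31 measured members fell (18 adjusted over the list alone; camera adjusted p = 9.6e-05, adjusted p = 0.11 with an estimated correlation). Among the DNA repair genes spike-in scaling put 20 down, at a median of -1.25 log2. Mitotic genes again did not move as a group (camera adjusted p = 0.58). Spike-in scaling put 17 down among the mitotic genes, at a median of -0.6 log2. Of the estrogen-responsive genes, 3 of 28 measured members rose and 15 fell (6 and 16 adjusted over the list alone; camera adjusted p = 0.0057, adjusted p = 0.18 with an estimated correlation). Among the estrogen-responsive genes spike-in scaling put 17 down, at a median of -1.23 log2. MYB was down 3.34 ± 0.17 (adjusted p = 1.9e-07). Of the luminal identity genes, 3 of 19 measured members rose and 11 fell (3 and 11 adjusted over the list alone; camera adjusted p = 0.032, adjusted p = 0.27 with an estimated correlation). Spike-in scaling put 2 up and 12 down among the luminal genes, at a median of -1.42 log2. Of the cholesterol synthesis genes, 1 of 17 measured members rose and 11 fell (2 and 11 adjusted over the list alone; camera adjusted p = 0.0017, adjusted p = 0.11 with an estimated correlation). Among the cholesterol genes spike-in scaling put 12 down, at a median of -1.38 log2.

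Most named targets moved in sangivamycin as in ARC, with other sizes. CCNT1 rose by 1.27 ± 0.15 (adjusted p = 5.8e-05) and HEXIM1 by 1.13 ± 0.11 (adjusted p = 1.6e-05), while CDK9 did not pass at -0.26 ± 0.19 (adjusted p = 0.32; adjusted p = 0.016 without sangivamycin array 1). The P-TEFb list did not pass (camera adjusted p = 0.36). Spike-in scaling put 1 up and 7 down in the P-TEFb list, at a median of -0.36 log2. PRKCD fell from 904.6 ± 53.5 to 94.39 ± 31.3, by 3.09 ± 0.26 (adjusted p = 6.6e-06), and PRKCE by 3.17 ± 0.44 (adjusted p = 2e-04), while PRKCA did not pass at 0.54 ± 0.43 (adjusted p = 0.34). PRKCE read 16.83 ± 11.7 in sangivamycin, under the filter value of 53.66, so the size of its fall is uncertain. In the protein kinase C list 6 of 12 measured members fell (6 adjusted over the list alone; camera adjusted p = 0.066), and the list passed without sangivamycin array 1 (adjusted p = 0.025), with no filter (adjusted p = 0.026) and with spike-in scaling (adjusted p = 0.046). In the protein kinase C list spike-in scaling put 7 down, at a median of -1.38 log2. BIRC5 rose by 2.74 ± 0.16 (adjusted p = 5.3e-07), MCL1 by 0.78 ± 0.11 (adjusted p = 0.00017) and MDM2 by 0.89 ± 0.15 (adjusted p = 0.00082). BCL2 fell by 1.97 ± 0.17 (adjusted p = 6.3e-06), CCND1 by 1.57 ± 0.12 (adjusted p = 4.2e-06), SLC29A1 by 2.67 ± 0.43 (adjusted p = 0.00053), ADK by 0.65 ± 0.11 (adjusted p = 0.00065), TOP2B by 0.73 ± 0.11 (adjusted p = 0.00043) and TOP2A by 0.57 ± 0.14 (adjusted p = 0.0071; adjusted p = 0.056 without control array 1). Single arrays moved 2 of these: SLC29A1 to -1.73 log2 without sangivamycin array 2 and -3.61 without array 1, and TOP2A to -0.36 without array 2. POLR2A did not pass at -0.12 ± 0.19 (adjusted p = 0.67). With spike-in scaling the calls of CCNT1, HEXIM1, MCL1 and MDM2 ended in sangivamycin, and without a trend in the prior variance that of TOP2A. Of the fibroblast and stromal genes, high on 1 sangivamycin array only, limma called 0 of 13 measured members, and 0 at an unadjusted p below 0.05 (camera adjusted p = 0.17). Spike-in scaling put no member past the threshold among the stromal genes, at a median of 0.16 log2. The stromal list passed without sangivamycin array 1 (adjusted p = 0.0026) and with spike-in scaling (adjusted p = 0.023). Another probe set of FNIP1, MYB, ADK, MDM2 and TOP2A moved the opposite way past the threshold in sangivamycin. No other probe set of PRKCE passed in sangivamycin. The leukocyte list passed (3 of 13 measured members rose; camera adjusted p = 0.033, adjusted p = 0.28 with an estimated correlation), but not without sangivamycin array 2 (adjusted p = 0.068), sangivamycin array 1 (adjusted p = 0.067) or control array 1 (adjusted p = 0.055), nor with quantile normalization (adjusted p = 0.093). Among the leukocyte genes spike-in scaling put no member past the threshold, at a median of 0.49 log2.

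Doxorubicin shut down the mitotic program, which did not move as a group in either nucleoside. BIRC5 fell from 1840 ± 48.8 to 492.6 ± 21.5, by 1.87 ± 0.16 (adjusted p = 3.8e-06), and TOP2A, the drug's target, from 7460 ± 82.1 to 1129 ± 15.1, by 2.71 ± 0.14 (adjusted p = 6.4e-08). Of the G2/M and mitosis genes, 42 of 43 measured members fell (1 and 42 adjusted over the list alone). Their median change was -2.71 log2 (camera adjusted p = 1.7e-34, adjusted p = 0.017 with an estimated correlation). The p53 targets rose here as well. GDF15 rose to 20870 ± 1640 (6.48 ± 0.11, adjusted p = 5.4e-11) and CDKN1A to 21190 ± 2600 (4.61 ± 0.13, adjusted p = 2e-09). The 10 largest rises, from 5.74 to 6.54 log2, were those of PSG4, GDF15, PSG7, PSG9, FOSL1, NTN4, PSG6, LACC1, KRT15 and CCDC3. The 10 largest falls, from -4.05 to -5.75, were those of UHRF1, NMU, FBXO17, MT1HL1, MUC1, BUB1B, DCLRE1A, KIF14, ORC1 and RRM2. Of each 10, 6 had a lower signal under 53.66, so their size and order are uncertain.

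Of the p53 targets in doxorubicin, 27 of 28 measured members rose (27 adjusted over the list alone; camera adjusted p = 1.4e-24, adjusted p = 0.017 with an estimated correlation). TP53I3 was up 5.63 ± 0.12 (adjusted p = 2.5e-10) and FAS up 4.61 ± 0.13 (adjusted p = 2e-09). Of the pro-apoptotic genes, 7 of 18 measured members rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0019, adjusted p = 0.16 with an estimated correlation). Spike-in scaling put 7 up among the pro-apoptotic genes, at a median of 0.91 log2. TNFRSF10B was up 3.82 ± 0.16 (adjusted p = 2.1e-08). TNFRSF10B, FAS, BAX, BBC3 and PMAIP1 are in the p53 target list too, so the pro-apoptotic result is not separate from that of the p53 targets. Of the DNA replication genes, 29 of 31 measured members fell (29 adjusted over the list alone; camera adjusted p = 3.8e-21, adjusted p = 0.031 with an estimated correlation). Among the replication genes spike-in scaling put 1 up and 24 down, at a median of -1.6 log2. MCM2 was down 3.71 ± 0.12 (adjusted p = 3.1e-09). Of the G1/S cyclins and E2F targets, 3 of 24 measured members rose and 17 fell (4 and 17 adjusted over the list alone; camera adjusted p = 1.3e-06, adjusted p = 0.11 with an estimated correlation). Of the DNA repair genes, 1 of 31 measured members rose and 24 fell (1 and 26 adjusted over the list alone; camera adjusted p = 2.1e-11, adjusted p = 0.051 with an estimated correlation). Spike-in scaling put 1 up and 14 down among the DNA repair genes, at a median of -0.92 log2. CHEK1 was down 3.84 ± 0.18 (adjusted p = 3.5e-08). Short-lived transcripts rose here too, since 31 of 43 measured members rose and 3 fell (31 and 4 adjusted over the list alone; camera adjusted p = 1.5e-09, adjusted p = 0.11 with an estimated correlation). Of the NF-kappaB targets, 9 of 20 measured members rose (9 adjusted over the list alone; camera adjusted p = 0.0021, adjusted p = 0.13 with an estimated correlation). Of the splicing factors, 3 of 34 measured members rose and 19 fell (4 and 22 adjusted over the list alone; camera adjusted p = 1.8e-05, adjusted p = 0.28 with an estimated correlation). Among the splicing factors spike-in scaling put 3 up and 7 down, at a median of -0.05 log2. SRSF7 was down 1.43 ± 0.1 (adjusted p = 8.9e-07). Of the ribosome biogenesis genes, 2 of 32 measured members rose and 21 fell (2 and 22 adjusted over the list alone; camera adjusted p = 7.8e-07, adjusted p = 0.057 with an estimated correlation). Spike-in scaling put 1 up and 1 down among the ribosome biogenesis genes, at a median of -0.3 log2. Of the glycolysis genes, 11 of 19 measured members fell (12 adjusted over the list alone; camera adjusted p = 5.2e-06, adjusted p = 0.18 with an estimated correlation). Among the glycolysis genes spike-in scaling put 5 down, at a median of -0.24 log2. Of the nuclear-encoded oxidative phosphorylation genes, 1 of 37 measured members rose and 21 fell (1 and 22 adjusted over the list alone; camera adjusted p = 3.1e-05, adjusted p = 0.34 with an estimated correlation), a call that ended with spike-in scaling (adjusted p = 0.09). Spike-in scaling put no member past the threshold among the oxidative phosphorylation genes, at a median of -0.06 log2. The integrated stress response did not move as a whole (8 of 20 measured members rose and 9 fell; camera adjusted p = 0.86), and neither did the estrogen-responsive genes (6 of 28 measured members rose and 10 fell; camera adjusted p = 0.56) or the histones (camera adjusted p = 0.39). Among the stress response genes spike-in scaling put 8 up and 2 down, at a median of -0.05 log2. Spike-in scaling put 5 up and 1 down among the estrogen-responsive genes, at a median of 0.11 log2. Among the histones spike-in scaling put 4 up and 2 down, at a median of 0.53 log2.

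Among the other named targets in doxorubicin, POLR2A rose from 1322 ± 192 to 6128 ± 1280 (2.19 ± 0.19, adjusted p = 4.4e-06) on the probe set used. Neither of its 2 other probe sets passed. MDM2 rose by 1.98 ± 0.15 (adjusted p = 1.5e-06), MCL1 by 1.09 ± 0.11 (adjusted p = 1e-05), HEXIM1 by 0.84 ± 0.11 (adjusted p = 1e-04) and CCNT1 by 0.71 ± 0.15 (adjusted p = 0.0026), while CDK9 did not pass at 0.3 ± 0.19 (adjusted p = 0.28). The P-TEFb list did not pass (camera adjusted p = 0.061), though it did without doxorubicin array 2 (adjusted p = 0.027), with no filter (adjusted p = 0.04) and with quantile normalization (adjusted p = 0.039). Spike-in scaling put 8 up in the P-TEFb list, at a median of 0.9 log2. MYC fell by 1.58 ± 0.12 (adjusted p = 1.7e-06), ESR1 by 0.79 ± 0.12 (adjusted p = 0.00037), BCL2 by 2.44 ± 0.17 (adjusted p = 6e-07) and SLC29A1 by 2.52 ± 0.43 (adjusted p = 0.00069). PRKCA rose by 1.5 ± 0.43 (adjusted p = 0.017; adjusted p = 0.14 without control array 2), whereas PRKCD and PRKCE did not pass at 0.09 ± 0.26 (adjusted p = 0.85) and -0.86 ± 0.44 (adjusted p = 0.16). CCND1 passed at 0.39 ± 0.12 (adjusted p = 0.03), but not without any 1 of the control or doxorubicin arrays (adjusted p = 0.2 without control array 1). ADK and TOP2B did not pass at 0.03 ± 0.11 (adjusted p = 0.85) and -0.28 ± 0.11 (adjusted p = 0.074), although TOP2B did with either sangivamycin array left out of the fit (adjusted p = 0.025). With only the 2 groups in the fit TOP2B (adjusted p = 0.023) and PRKCE (adjusted p = 0.035) passed. The other probe set of ADK passed in the same direction. No other probe set of ESR1, CCNT1, PRKCA or CCND1 passed in doxorubicin. With spike-in scaling the calls of ESR1 and CCND1 ended in doxorubicin, without a trend in the prior variance that of CCND1, and with quantile normalization that of PRKCA.

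**Figure D4:**
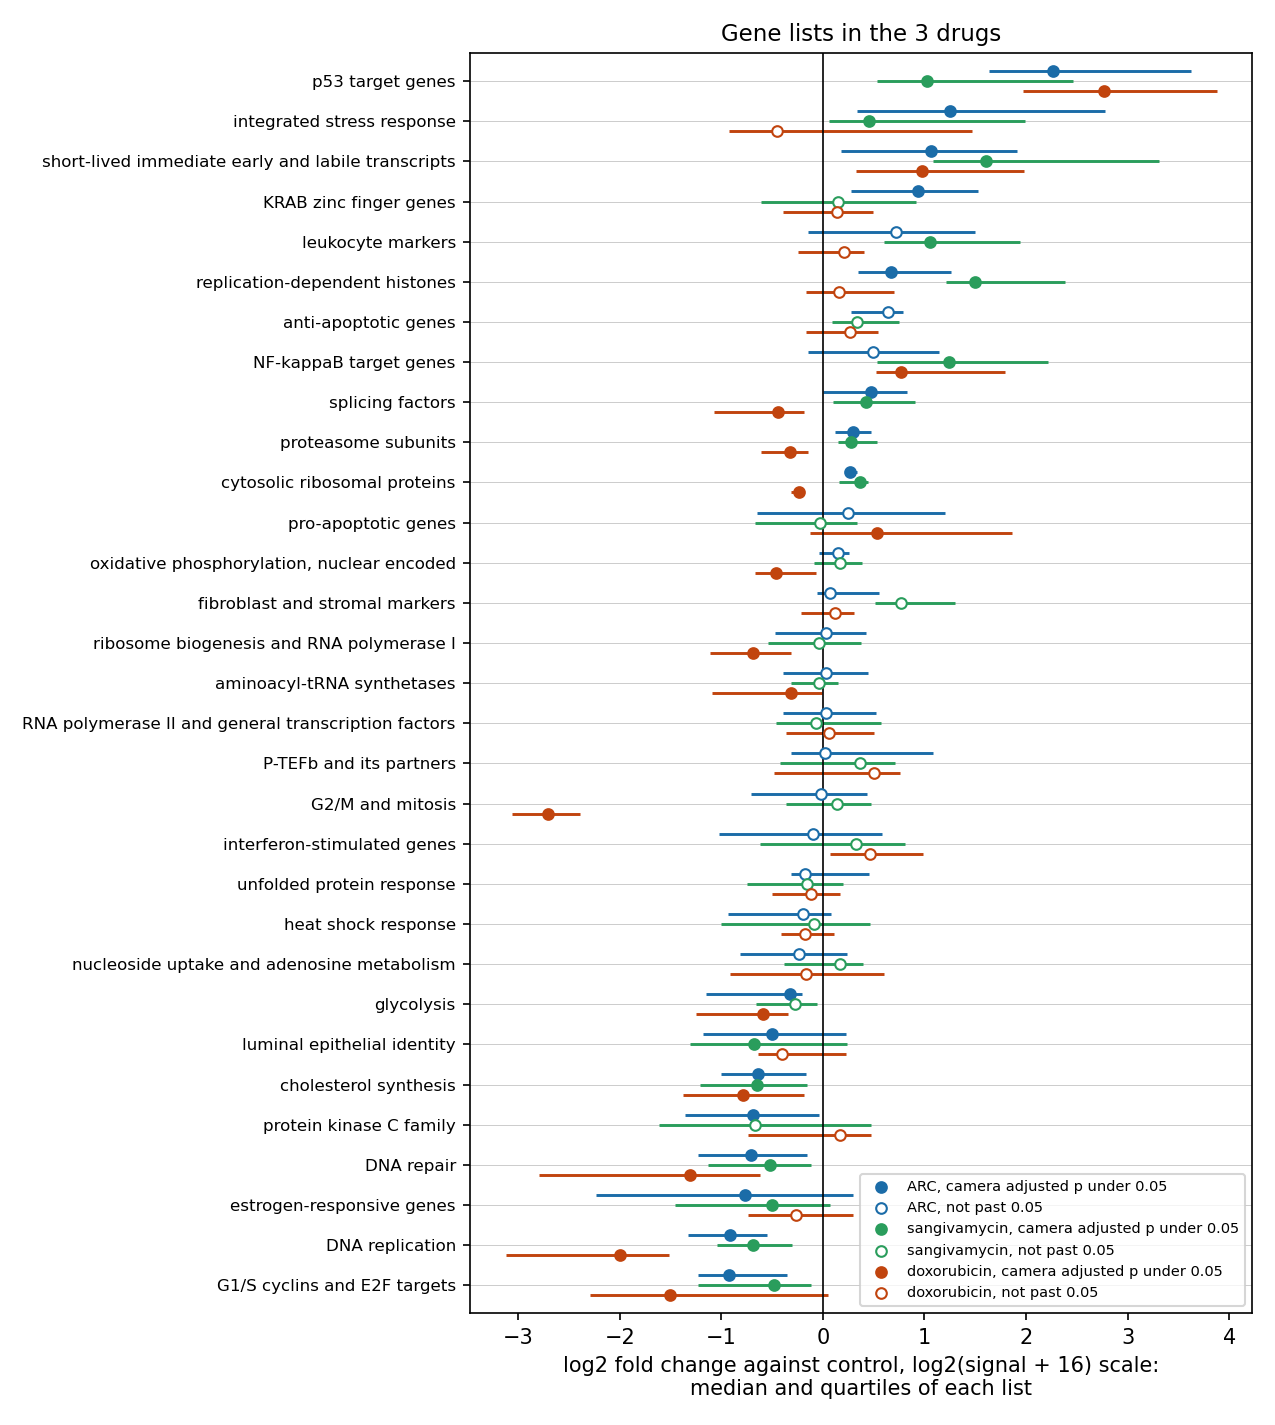
Median and quartiles of the log2 fold change against control for each of 31 gene lists in ARC, sangivamycin and doxorubicin, with filled points for a camera adjusted p under 0.05. The p53 targets lie above 0 in all 3 drugs, and the mitotic genes lie near 0 in the nucleosides and at -2.71 in doxorubicin.

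The ARC profile lay closer to the sangivamycin profile than to the doxorubicin profile. Across the 16018 genes the fold changes against control correlated at 0.721 between ARC and sangivamycin, 0.342 between ARC and doxorubicin and 0.265 between sangivamycin and doxorubicin. The comparisons share their controls, so noise adds to each value: in 20 simulations with no change in any group, the mean correlation was 0.499 to 0.501 and the mean covariance of the fold changes 0.086. The measured covariance exceeded that by 0.665 between ARC and sangivamycin, 0.27 between ARC and doxorubicin and 0.201 between sangivamycin and doxorubicin. ARC and sangivamycin both changed 3823 genes, of which 1451 rose in both, 2263 fell in both and 109 went opposite ways. Unrelated calls would put 398.7, 747.2 and 1092 genes there. ARC and doxorubicin both changed 3050 genes, 68.2% of them in the same direction, with 811 up in both, 1270 down in both and 969 opposite. For that pair unrelated calls would put 419, 631.4 and 1035 genes there. Sangivamycin and doxorubicin both changed 2841 genes, 60.9% of them in the same direction. There 692 rose in both, 1037 fell in both and 1112 went opposite ways, against 418.4, 631.6 and 1034 for unrelated calls. In the simulations at most 1 gene was called in both drugs. Noise in the shared controls may add to these overlaps.

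**Figure D5:**
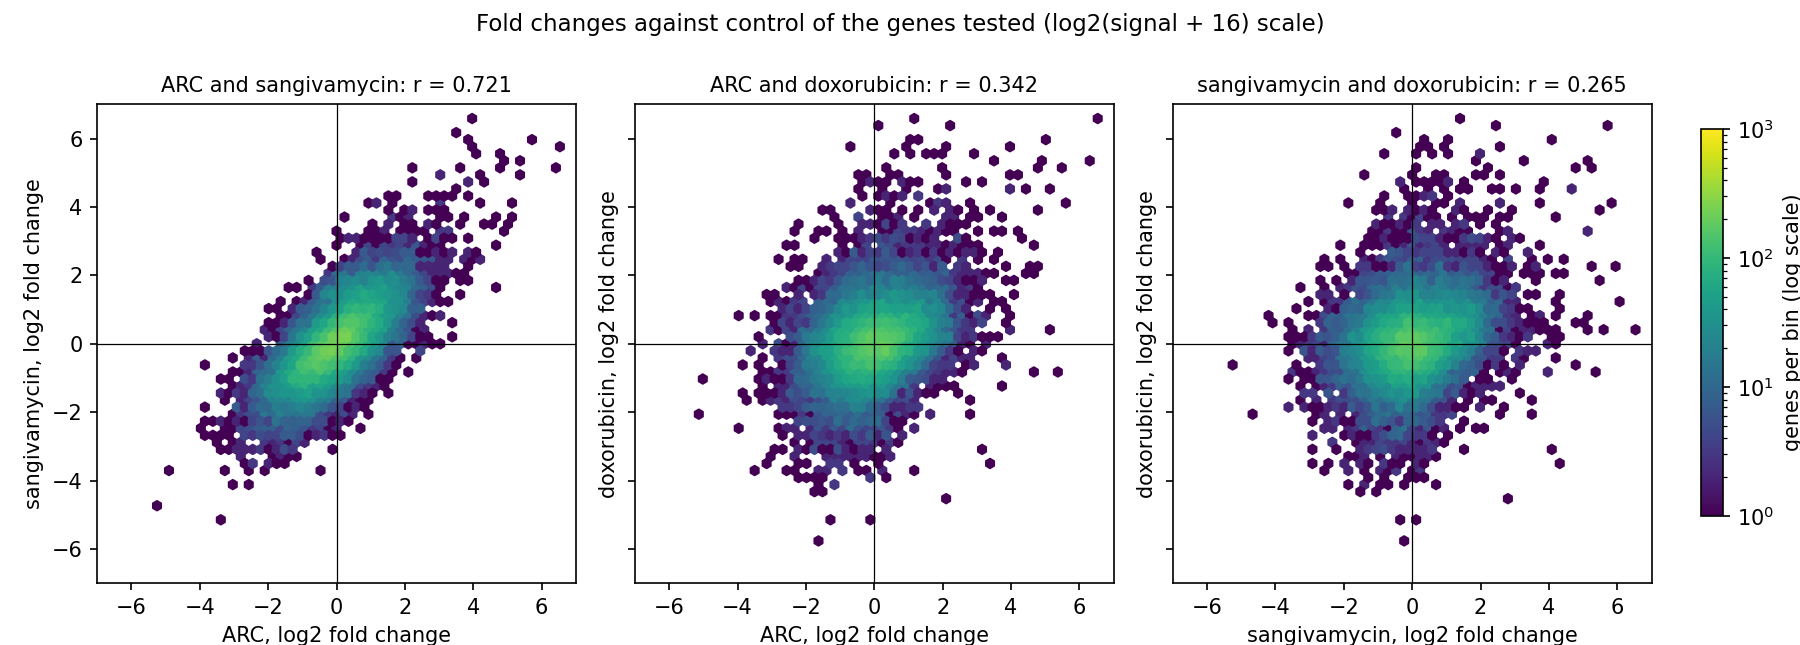
Log2 fold changes against control of the genes tested, binned into hexagons coloured by the number of genes (log scale), for each pair of drugs. The genes follow the diagonal most closely for ARC and sangivamycin, where the correlation was 0.721.

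Set directly against each other, ARC and sangivamycin differed in p53 targets, which were higher in ARC (adjusted p = 0.018 with an estimated correlation). Labile transcripts were higher in sangivamycin, a call that ended with an estimated correlation (adjusted p = 0.097). CDKN1A read 29840 ± 3570 in ARC and 10960 ± 1330 in sangivamycin (1.44 ± 0.13, adjusted p = 6.2e-05), and the p53 target TP53I3 differed by 1.69 ± 0.12 (adjusted p = 2.4e-05). BIRC5 read 4324 ± 68 in ARC and 12630 ± 3500 in sangivamycin (-1.51 ± 0.16, adjusted p = 0.00013) on the probe set used. None of its 3 other probe sets passed between the compounds. In all 3739 genes differed, 1918 higher and 1821 lower in ARC, and 1426 of them by at least 2-fold. Without sangivamycin array 2 the count was 3510, with 2045 higher and 1465 lower and 2863 shared, without ARC array 1 it was 1932 and without ARC array 2 it was 2234. With spike-in scaling, which shifted the median gene by 0.438 log2, 93.2% of 1975 genes were higher in ARC, against 51.3%.

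Of the p53 targets, 25 of 28 measured members were higher and 1 lower in ARC than in sangivamycin (26 and 1 adjusted over the list alone). Among the p53 targets spike-in scaling put 25 higher, at a median of 1.7 log2. The median difference was 1.24 log2 (camera adjusted p = 5.1e-17, adjusted p = 0.018 with an estimated correlation). TP53INP1 differed by 1.98 ± 0.14 (adjusted p = 2.4e-05), SESN2 by 1.72 ± 0.14 (adjusted p = 3.3e-05) and FAS by 1.44 ± 0.13 (adjusted p = 6.2e-05). KRAB zinc finger genes were also higher in ARC, since 18 of 43 measured members were higher and 2 lower (21 and 2 adjusted over the list alone; camera adjusted p = 6.5e-08, adjusted p = 0.059 with an estimated correlation). Spike-in scaling put 19 higher among the KRAB genes, at a median of 1.2 log2. ZNF140 differed by 1.25 ± 0.14 (adjusted p = 0.00017). Of the integrated stress response genes, 9 of 20 measured members were higher and 2 lower (11 and 3 adjusted over the list alone; camera adjusted p = 0.0018, adjusted p = 0.11 with an estimated correlation). Among the stress response genes spike-in scaling put 10 higher, at a median of 1 log2. DDIT4 differed by 1 ± 0.11 (adjusted p = 0.00015). Of the short-lived transcripts, 3 of 43 measured members were higher and 26 lower (4 and 31 adjusted over the list alone). Spike-in scaling put 3 higher and 14 lower among the short-lived transcripts, at a median of -0.35 log2. Their median difference was -0.84 log2 (camera adjusted p = 1e-11, adjusted p = 0.097 with an estimated correlation). Of the NF-kappaB targets, 6 of 20 measured members were lower (7 adjusted over the list alone; camera adjusted p = 0.00057, adjusted p = 0.11 with an estimated correlation). Among the NF-kappaB targets spike-in scaling put 3 lower, at a median of -0.43 log2. NFKBIA differed by -1.57 ± 0.12 (adjusted p = 2.4e-05). Of the histones, 10 of 24 measured members were lower (14 adjusted over the list alone; camera adjusted p = 7.8e-06, adjusted p = 0.13 with an estimated correlation). Spike-in scaling put no member past the threshold among the histones, at a median of -0.28 log2. The 10 genes furthest above sangivamycin, from 2.85 to 3.18 log2, were SLX4, GTF2IRD2B, MGAM, CEL, GTF2IP20, PYGM, LAT2, PIAS4, MAPK8IP3 and LCAT (for LCAT, adjusted p = 0.06 without ARC array 1). The 10 furthest below, from -2.93 to -3.36, were HNRNPD-DT, FOXA2, HBB, IL1A, COX3, FOXA1, TCIM, LINC01620, AGBL3 and TMEM200B. In 6 of the first 10 and 3 of the second the lower signal lay under 53.66, so their size and order are uncertain. CEL fell back to 1.88 log2 without sangivamycin array 1. HBB stood at this place only through sangivamycin array 2 (-0.83 log2, adjusted p = 0.28 without it), LINC01620 lost its call with no filter on dim probe sets, and TCIM with log2(value + 1) (adjusted p = 0.078).

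ARC and sangivamycin were close on a part of the transcriptome. For 6270 of the 16018 genes (39.1%) the 95% interval of the difference lay within 2-fold either way, and for 7163 genes the data settled neither a difference nor such closeness. Some of the 6270 were also called different, by less than 2-fold. The share was taken over all genes tested, changed against control or not, and was not computed for other pairs of groups. Of 8150 genes that either compound changed against control, 3344 (41%) differed between them. Of the 3823 that both changed, 1168 differed, 624 with the larger change in ARC and 544 with the larger change in sangivamycin. Lists of mitotic genes (camera adjusted p = 0.11), P-TEFb and its partners (camera adjusted p = 0.14), the protein kinase C family (camera adjusted p = 0.92), splicing factors (camera adjusted p = 0.37) and estrogen-responsive genes (camera adjusted p = 0.43) did not separate the compounds as groups. Among the mitotic genes spike-in scaling put 3 higher, at a median of 0.36 log2. Spike-in scaling put 4 higher in the P-TEFb list, at a median of 0.84 log2. In the protein kinase C list spike-in scaling put 3 higher, at a median of 0.32 log2. Spike-in scaling put 6 higher among the splicing factors, at a median of 0.56 log2. Among the estrogen-responsive genes spike-in scaling put 6 higher and 2 lower, at a median of 0.29 log2. MCL1 did not differ on the probe set used (-0.06 ± 0.11, adjusted p = 0.75, 95% interval -0.29 to 0.18), though 1 of its 5 other probe sets was lower in ARC past the threshold. TOP2B (-0.1 ± 0.11, adjusted p = 0.56, 95% interval -0.35 to 0.14) and POLR2A (-0.18 ± 0.19, adjusted p = 0.55, 95% interval -0.6 to 0.24) did not differ either. PRKCA left a wide interval (-0.57 ± 0.43, adjusted p = 0.38, 95% interval -1.51 to 0.37). SLC29A1 did not pass at 0.11 ± 0.43 (adjusted p = 0.88; 95% interval -0.83 to 1.05), with 1.05 log2 (adjusted p = 0.0015) without sangivamycin array 1 and -0.83 (adjusted p = 0.0049) without array 2. TOP2A did not pass at -0.32 ± 0.14 (adjusted p = 0.12; -0.54, adjusted p = 0.0051 without sangivamycin array 2), though 1 of its 2 other probe sets was lower in ARC past the threshold.

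Single targets did differ between ARC and sangivamycin. CDK9 was higher in ARC by 1.19 ± 0.19 (adjusted p = 0.0014), MDM2 by 1.49 ± 0.15 (adjusted p = 9.9e-05), ESR1 by 1.08 ± 0.12 (adjusted p = 0.00019) and PRKCD by 1.66 ± 0.26 (adjusted p = 0.0012). PRKCE was higher by 1.61 ± 0.44 (adjusted p = 0.021; adjusted p = 0.11 without ARC array 1), CCNT1 by 0.56 ± 0.15 (adjusted p = 0.018; adjusted p = 0.1 without ARC array 2), CCND1 by 0.6 ± 0.12 (adjusted p = 0.0056; adjusted p = 0.063 without ARC array 2) and ADK by 0.45 ± 0.11 (adjusted p = 0.011; adjusted p = 0.089 without ARC array 1). The size for PRKCE is uncertain, since it read 16.83 ± 11.7 in sangivamycin, under 53.66. HEXIM1 was lower in ARC at -0.67 ± 0.11 (adjusted p = 0.0014), BCL2 at -0.74 ± 0.17 (adjusted p = 0.0082; adjusted p = 0.071 without ARC array 2) and MYC at -0.44 ± 0.12 (adjusted p = 0.024; adjusted p = 0.16 without ARC array 2). With spike-in scaling the calls of BIRC5, ADK, HEXIM1, BCL2 and MYC ended between ARC and sangivamycin. Without a trend in the prior variance those of HBB, CCNT1, CCND1, ADK, BCL2 and MYC ended, and with only the 2 groups in the fit those of HBB, PRKCE, CCNT1, ADK, BCL2 and MYC. Another probe set of ESR1, ADK and PRKCE differed the opposite way past the threshold. No other probe set of CDK9, HEXIM1 or BCL2 passed between ARC and sangivamycin.

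ARC and doxorubicin parted over the cell cycle and over 1 probe set of POLR2A, the largest subunit of RNA polymerase II. Neither of the 2 other POLR2A probe sets passed. Of the G2/M and mitosis genes, 42 of 43 measured members were higher and 1 lower in ARC (42 and 1 adjusted over the list alone), with a median of 2.46 log2 (camera adjusted p = 5.5e-27, adjusted p = 0.017 with an estimated correlation). BIRC5 read 4324 ± 68 in ARC and 492.6 ± 21.5 in doxorubicin (3.09 ± 0.16, adjusted p = 7.4e-08), and POLR2A read 1071 ± 91.1 and 6128 ± 1280 (-2.49 ± 0.19, adjusted p = 1.3e-06). In all 7242 genes differed, 3363 higher and 3879 lower in ARC, and with spike-in scaling 14.3% of 5756 were higher, against 46.4%, at a median shift of -0.536 log2. The 10 genes furthest above doxorubicin, from 4.61 to 6.83 log2, were MT1X, MT1HL1, MT1H, ND6, CYP4F2, NMU, SLC7A11, MT2A, PLK1 and CYP4F3. The 10 furthest below, from -5.28 to -6.52, were CCDC3, PSG9, FGFR3, HSPG2, UPK2, PSG4, TMEM158, RBPMS2, KAT2B and ABHD15. The lower signal lay under 53.66 in 6 of each 10, whose size and order are uncertain.

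The p53 targets, up in both drugs, did not separate ARC from doxorubicin as a list (7 of 28 measured members were higher and 13 lower; 8 and 14 adjusted over the list alone; camera adjusted p = 0.22), though with quantile normalization they did, lower in ARC (adjusted p = 0.035). Spike-in scaling put 15 lower among the p53 targets, at a median of -0.91 log2. Short-lived transcripts did not either (camera adjusted p = 0.73). Among the short-lived transcripts spike-in scaling put 5 higher and 22 lower, at a median of -1.27 log2. Replication genes lay higher in ARC, where 26 of 31 measured members were higher and 3 lower (27 and 3 adjusted over the list alone; camera adjusted p = 1.2e-09, adjusted p = 0.06 with an estimated correlation). Spike-in scaling put 12 higher and 3 lower among the replication genes, at a median of 0.68 log2. So did splicing factors, where 26 of 34 measured members were higher and 1 lower (26 and 1 adjusted over the list alone; camera adjusted p = 7.5e-11, adjusted p = 0.15 with an estimated correlation). Among the splicing factors spike-in scaling put 13 higher and 1 lower, at a median of 0.47 log2. Integrated stress response genes did too, where 16 of 20 measured members were higher and 2 lower (16 and 2 adjusted over the list alone; camera adjusted p = 1.5e-06, adjusted p = 0.059 with an estimated correlation). Spike-in scaling put 10 higher and 2 lower among the stress response genes, at a median of 0.79 log2. Of the estrogen-responsive genes, 5 of 28 measured members were higher and 16 lower (5 and 16 adjusted over the list alone; camera adjusted p = 0.0024, adjusted p = 0.15 with an estimated correlation). Among the estrogen-responsive genes spike-in scaling put 3 higher and 18 lower, at a median of -1.45 log2. TOP2A was higher in ARC by 1.81 ± 0.14 (adjusted p = 1.1e-06) and CCNT1 by 1.12 ± 0.15 (adjusted p = 7.2e-05). MYC was lower at -1.29 ± 0.12 (adjusted p = 6.2e-06), ESR1 at -1.68 ± 0.12 (adjusted p = 7.9e-07), PRKCD at -1.52 ± 0.26 (adjusted p = 0.00057), CCND1 at -1.36 ± 0.12 (adjusted p = 4.5e-06), TOP2B at -0.55 ± 0.11 (adjusted p = 0.002) and PRKCA at -1.53 ± 0.43 (adjusted p = 0.012; adjusted p = 0.093 without doxorubicin array 1). Smaller differences hung on single arrays: MCL1 at -0.36 ± 0.11 (adjusted p = 0.11 without ARC array 2), HEXIM1 at -0.38 ± 0.11 (adjusted p = 0.088 without ARC array 1), CDK9 at 0.64 ± 0.19 (adjusted p = 0.11 without doxorubicin array 2), CDKN1A at 0.49 ± 0.13 (adjusted p = 0.11 without ARC array 1) and MDM2 at 0.4 ± 0.15 (adjusted p = 0.21 without ARC array 2). PRKCE at -0.7 ± 0.44 (adjusted p = 0.23), ADK at -0.23 ± 0.11 (adjusted p = 0.11), SLC29A1 at -0.04 ± 0.43 (adjusted p = 0.95) and BCL2 at -0.27 ± 0.17 (adjusted p = 0.21) did not pass between ARC and doxorubicin, though another probe set of PRKCE and of ADK did in the same direction. With spike-in scaling the calls of CCNT1, CDK9, CDKN1A and MDM2 ended, and without a trend in the prior variance those of MCL1, HEXIM1, CDK9, CDKN1A and MDM2. ADK passed with quantile normalization (adjusted p = 0.02) and with spike-in scaling (adjusted p = 0.044), and another probe set of HEXIM1 differed the opposite way past the threshold. No other probe set of MCL1, CDK9 or PRKCA passed between ARC and doxorubicin.

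Sangivamycin and doxorubicin differed widely. BIRC5 read 12630 ± 3500 in sangivamycin and 492.6 ± 21.5 in doxorubicin (4.61 ± 0.16, adjusted p = 4.6e-09), ESR1 545.8 ± 28.7 and 3796 ± 430 (-2.76 ± 0.12, adjusted p = 1.8e-08), and PRKCD 94.39 ± 31.3 and 975.4 ± 247 (-3.17 ± 0.26, adjusted p = 1.8e-06). In all 7599 genes differed, 3555 higher and 4044 lower in sangivamycin, and 7230 did without sangivamycin array 2. With spike-in scaling 6.8% of 8193 genes were higher, against 46.8%, at a median shift of -0.983 log2. The 10 genes furthest above doxorubicin, from 5.21 to 7.76 log2, were MT1X, MT1H, MT1HL1, FNIP1, ND6, MT2A, UHRF1, ITPRID2, MT1F and RPPH1. The 10 furthest below, from -5.19 to -6.77, were PSG9, PRODH, DPYSL4, WHRN, NTN4, TP53I3, CCDC3, LACC1, AHNAK2 and PSG4. A lower signal under 53.66 makes the size and order uncertain for 4 of the first 10 and 2 of the second.

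Here the p53 targets did part the drugs, since 1 of 28 measured members were higher and 22 lower in sangivamycin (2 and 22 adjusted over the list alone; camera adjusted p = 3.6e-08, adjusted p = 0.051 with an estimated correlation). Spike-in scaling put 26 lower among the p53 targets, at a median of -2.35 log2. CDKN1A differed by -0.95 ± 0.13 (adjusted p = 0.00011) and MDM2 by -1.09 ± 0.15 (adjusted p = 9.9e-05). Of the mitotic genes, 42 of 43 measured members were higher and 1 lower (42 and 1 adjusted over the list alone; camera adjusted p = 5.7e-26, adjusted p = 0.017 with an estimated correlation). Among the mitotic genes spike-in scaling put 35 higher and 1 lower, at a median of 1.58 log2. Of the replication-dependent histones, 13 of 24 measured members were higher and 1 lower (15 and 2 adjusted over the list alone; camera adjusted p = 0.00079, adjusted p = 0.21 with an estimated correlation). Spike-in scaling put 6 higher and 5 lower among the histones, at a median of 0.38 log2. Short-lived transcripts lay higher in sangivamycin, where 25 of 43 measured members were higher and 9 lower (25 and 9 adjusted over the list alone; camera adjusted p = 0.00077, adjusted p = 0.26 with an estimated correlation). Among the short-lived transcripts spike-in scaling put 9 higher and 14 lower, at a median of -0.4 log2. TOP2A was higher in sangivamycin by 2.14 ± 0.14 (adjusted p = 2.8e-07). POLR2A was lower at -2.31 ± 0.19 (adjusted p = 1.9e-06), PRKCE at -2.31 ± 0.44 (adjusted p = 0.00098), CCND1 at -1.96 ± 0.12 (adjusted p = 2.4e-07), MYC at -0.85 ± 0.12 (adjusted p = 0.00014), ADK at -0.68 ± 0.11 (adjusted p = 0.00025) and TOP2B at -0.44 ± 0.11 (adjusted p = 0.0068). PRKCE read 16.83 ± 11.7 in sangivamycin, under 53.66, which leaves its size uncertain. Smaller differences again hung on single arrays: CCNT1 at 0.56 ± 0.15 (adjusted p = 0.069 without doxorubicin array 2), CDK9 at -0.55 ± 0.19 (adjusted p = 0.2 without sangivamycin array 2), BCL2 at 0.47 ± 0.17 (adjusted p = 0.19 without sangivamycin array 2), MCL1 at -0.31 ± 0.11 (adjusted p = 0.1 without doxorubicin array 1) and HEXIM1 at 0.29 ± 0.11 (adjusted p = 0.16 without sangivamycin array 2). SLC29A1 did not pass at -0.15 ± 0.43 (adjusted p = 0.8), with 0.79 log2 (adjusted p = 0.0021) without sangivamycin array 2 and -1.09 (adjusted p = 0.00041) without array 1, and neither did PRKCA at -0.96 ± 0.43 (adjusted p = 0.087). With spike-in scaling SLC29A1 passed at -1.24 (adjusted p = 0.0081) and PRKCA at -1.98 (adjusted p = 0.00095). PRKCA also passed with log2(value + 64) (adjusted p = 0.047) and without a trend (adjusted p = 0.033), and its other probe set passed in the same direction. With spike-in scaling the calls of CCNT1, BCL2 and HEXIM1 ended or turned, and without a trend in the prior variance those of TOP2B, CCNT1, CDK9, BCL2, MCL1 and HEXIM1 ended. Another probe set of FNIP1, ITPRID2, ESR1, MCL1 and MDM2 differed the opposite way past the threshold. No other probe set of POLR2A, PRKCE, ADK, CDK9 or HEXIM1 passed between sangivamycin and doxorubicin.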

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

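All tests in this part were chosen after the result they address had been seen.

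A part of the ribosomal RNA signals, on control probe sets that no comparison used, lay above the control arrays in the nucleosides. The 3' end of 18S rRNA read 5.64 times the control mean in ARC and 5.41 times in sangivamycin, and the ratio of its 3' to its 5' end 5.67 times and 4.74 times. That 3' end differed between arrays of a group, with 9219 and 4851 in ARC and 2465 and 11020 in sangivamycin against 1109 and 1384 in controls, so most of the sangivamycin mean came from array 2. The 3' end of 28S rRNA read 15 times and its middle 2.05 times the control mean in sangivamycin. The control signals of that 3' end, 11.67 and 22.5, lay under the filter value of 53.66, so the size of the rise is uncertain. Both arrays of the drug lay above both control arrays in each of these, but not in the other 5 of 6 signals in ARC or the other 3 of 6 in sangivamycin. The same held for the 18S ratio in doxorubicin, though at only 1.06 times the control mean.

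The 18S ratio was 3.64 and 5.65 on the ARC arrays and 4.62 and 3.15 on the sangivamycin arrays, against 0.827 and 0.811 in controls, and ND6 and RPPH1 rose on the same arrays. General degradation of messenger RNA would raise the 3'/5' ratio of actin too. That ratio changed by at most 0.39 log2 on both ARC arrays and sangivamycin array 1, which argues against it there. Actin is a messenger RNA, so its ratio cannot exclude degradation of ribosomal RNA alone. On sangivamycin array 2 the actin ratio changed by 2.21 log2, and degradation cannot be told apart. The scaling of the arrays is excluded, since with spike-in scaling the smallest rise of ND6 and RPPH1 in either drug was 3.75 log2. More label in RNA without a poly(A) tail would also raise the replication-dependent histones. At the assumed correlation that list passed, upward, in ARC and in sangivamycin and did not pass in doxorubicin. The test set for this question used an estimated correlation, with which the list in ARC had a camera adjusted p of 0.22. Only 8 of all 186 list tests passed in that setting, so a list that does not pass there cannot tell. No biological explanation was tested, and whether the drugs change these RNAs stays open.

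Sangivamycin array 2 held most stromal transcripts and HBB above every other array. Of 13 measured stromal genes 10 were highest there, as were 6 of 13 leukocyte genes, and HBB read 5454 against at most 173 elsewhere. Scaling does not account for it, since with spike-in scaling the stromal median still lay 1.81 log2 above that of sangivamycin array 1. An effect of the drug does not either, since on array 1 it lay -0.47 log2 from the controls. RNA from stromal cells alone would leave the blood gene HBB unaccounted for. RNA from other cells, stromal and blood cells included, and degraded RNA on that array both stay open. The actin ratio changed there by 2.21 log2, and no test separates them.

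ARC left p53 targets higher and short-lived transcripts lower than sangivamycin did. Sangivamycin array 2 is excluded as the source, since without it the p53 median of the difference was 1.23 log2 with 23 members higher, and the short-lived median -0.8 with 24 lower. With all arrays the short-lived list had an adjusted p of 0.097 with an estimated correlation. On the trimmed-mean scale the values argue against a stronger action of 1 compound on all genes. Of 1059 genes that both changed in the same direction and that differed between them, 53.7% changed more in ARC. That scale gives every array the same mean, and the share was not computed with spike-in scaling. There 93.2% of 1975 differing genes were higher in ARC, so this explanation is not excluded on that scale. A difference between the compounds in what they do at this dose and time was not tested further and stays open.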

How the results depend on the processing

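The rise of the p53 target list against control in each drug kept its direction and its side of the threshold under every alternative. So did the fall of the mitotic list in doxorubicin. The alternatives run for lists were no filter, quantile normalization, spike-in scaling, the block, 1 array left out and an estimated correlation. The median of the p53 list in sangivamycin shrank with spike-in scaling. The call of its member MDM2 in sangivamycin ended with that scaling (0.15 log2, adjusted p = 0.77). Leaving out 1 array at a time gave 3993 to 6962 genes changed by ARC, 3852 to 5961 by sangivamycin and 3905 to 6474 by doxorubicin, and 1932 to 4343 between ARC and sangivamycin, 5646 to 7977 between ARC and doxorubicin and 6050 to 7469 between sangivamycin and doxorubicin. The correlation of fold changes ranged from 0.661 to 0.743 for ARC with sangivamycin, 0.301 to 0.391 for ARC with doxorubicin and 0.227 to 0.317 for sangivamycin with doxorubicin with 1 array left out, and no alternative has a simulated value of its own. Of the 186 list tests 84 to 89 then passed, against 85.

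Some counts moved by over 1.5 times. Spike-in scaling gave 3426 genes for ARC, 3614 for doxorubicin and 1975 between ARC and sangivamycin. The spike-in signals differed within groups. They lay 0.456 and -0.282 log2 from the mean of all arrays in ARC and 0.414 and 0.78 in sangivamycin. In doxorubicin they lay at -0.726 and -0.358, and in controls at -0.211 and -0.073. Scaling to them adds that spread to every gene, beside a median residual SD of 0.26 log2. Whether it accounts for the lower counts was not tested. Testing all 39818 probe sets gave 11416 for ARC, 13549 for sangivamycin, 9310 for doxorubicin, 7026 between ARC and sangivamycin, 13960 between ARC and doxorubicin and 16192 between sangivamycin and doxorubicin, since more items were tested. Between ARC and sangivamycin the count was 2252 without a trend in the prior variance, the cause not tested, and with fewer samples in the fit it was 2212 for only the 2 groups, 1932 without ARC array 1 and 2234 without ARC array 2. Sangivamycin against control gave 3852 without control array 1 and 3968 without control array 2, again with fewer samples. Fewer samples did not always lower a count, since with only the 2 groups 7097 genes changed in ARC and 6778 in doxorubicin against control. What lowered the other counts was not tested. With the correlation estimated from the data, 8 list tests passed, so most list calls rest on the assumed correlation.

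Of 271 named gene values, 247 kept their call with spike-in scaling, 250 without a trend, 264 with quantile normalization and 258 to 265 with 1 array left out. These turned round with spike-in scaling: MYC to 0.07 log2 between ARC and sangivamycin, CDKN1A to -0.13 and MDM2 to -0.22 between ARC and doxorubicin, and HEXIM1 to -0.84, CCNT1 to -0.57 and BCL2 to -0.65 between sangivamycin and doxorubicin. SLC29A1, not past the threshold, turned with the sangivamycin array left out. Between ARC and sangivamycin it was 1.05 without array 1 and -0.83 without array 2, and between sangivamycin and doxorubicin -1.09 and 0.79. LINC01620 turned to 0.38 between ARC and sangivamycin with no filter, where another probe set stood for it; the cause was not tested for the others.

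With the array number as a replicate block, 5868 genes changed in ARC, 5829 in sangivamycin and 5449 in doxorubicin, and 3493, 7074 and 7475 differed between ARC and sangivamycin, ARC and doxorubicin, and sangivamycin and doxorubicin. Deviations of arrays with the same number correlated at -0.074 to 0.05 between groups, so no deviation common to them was seen across genes. The sources used here do not say what the number stands for. The block ended 3 of the 271 named calls and none of the 71 list results.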

Other observations

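Metallothioneins, which bind zinc and other metals, separated the nucleosides from doxorubicin. These genes and those of the next 2 paragraphs were chosen after their values had been seen, outside the naming rule. Of 9 measured members, 7 rose in ARC with a median of 2.34 log2 and 7 rose in sangivamycin with a median of 2.76, while 6 fell in doxorubicin with a median of -1.67. MT2A went from 2160 ± 250 in controls to 14840 in ARC, 25430 in sangivamycin and 498.9 in doxorubicin (n = 2 arrays each). The zinc exporter SLC30A1 rose from 246.1 to 7496 in ARC, 11600 in sangivamycin and 3883 in doxorubicin. The medians of the metallothioneins were 2.12, 2.02 and -1.31 with spike-in scaling. Their probe sets may read several near-identical genes, so which member moved is uncertain.

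Pregnancy-specific glycoproteins rose with doxorubicin. Of 9 measured members 7 rose there with a median of 2.94 log2, against 2 in ARC and 3 in sangivamycin, and PSG9 went from 83.4 to 7706. These genes too are near-identical. Among 7 mitochondrially encoded genes measured, 2 rose and 2 fell in ARC. In sangivamycin 2 rose and 0 fell, and in doxorubicin 0 rose and 1 fell. In ARC ND6 rose from 1452 to 58210 and ND2 by 0.61 log2 (adjusted p = 0.016). COX3 fell there from 2763 to 186.5, and ND4 changed by -1.29 (adjusted p = 3e-04). In controls ATP6, COX1, COX2, ND2 and ND4 read 48330 to 72010, far above the COX3 probe set. Whether that probe set reads the main COX3 transcript is therefore uncertain.

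Probe sets of the same gene moved in opposite directions in the nucleosides. Of 8041 genes with several probe sets, 275 had both a rise and a fall in ARC (3.42%), 623 in sangivamycin (7.75%) and 42 in doxorubicin (0.522%). Without sangivamycin array 2 the sangivamycin count was 570, with 432 of them shared. For ITPRID2, 1 probe set changed by 4.77 log2 in sangivamycin and another by -2. No test of which transcripts the probe sets read was made here.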
